A study of Mus musculus with 16 samples.

How the data were processed

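The study measured RNA from snap-frozen mouse tibialis anterior in 16 libraries: 2 control and 2 cachectic libraries for each of 4 tumour models (8 groups). Per the labels' protocols, total RNA was purified with Trizol, ribosomal RNA was depleted, and libraries were prepared with standard Illumina protocols. The submitters' processing notes name the GRCm38 genome build, featureCounts 1.4.5 and limma; the aligner, the annotation used for counting, the handling of strand and the filter on low values are not given in the sources used here. The authors deposited 1 table of log2 values, with a column per library; 11990 of its genes carried a symbol, 31 did not, and 2 shared a symbol. The values showed how they were made: raising 2 to each value, multiplying by the library total that the lowest values imply and subtracting 0.5 gave a whole number of reads for 100% of the values (tolerance 1e-04). The deposited log2 values are therefore log2 reads per 1000000 reads of the listed genes, with 0.5 added to each count and 1 to the total, the formula of voom, and no scaling between libraries beyond the total. Each gene's change is therefore relative to the sum of the listed genes in its library, and a fall of very abundant transcripts raises the value of all others. Changes of genes with few reads are understated by the added 0.5.

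The recovered totals were 28584279 to 46972882 reads per library, so counting error was small beside the spread between replicates: the chi-squared statistic per degree of freedom between 2 replicates was 9.76 to 185, and no pair agreed within counting noise. Each column was matched to its sample by the number in the sample's description, and groups and replicate numbers were taken from the sample titles; every sample was assigned. Genes with a log2 value of at least 0 in at least 2 libraries were to be kept, which all listed genes were. A single limma fit (limma 3.58.1, R 4.3.3) on the deposited values gave each of the 8 groups its own mean and shared 1 estimate of the spread, moderated with a trend on expression (lmFit, contrasts.fit and eBayes). The contrasts were cachectic minus control in each model, their mean over the 4 models, an F test of the 3 differences between the 4 effects, and the 6 differences between pairs of models. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and genes with an adjusted p under 0.05 were called. The median standard error of a log2 change was 0.192 within a model and 0.0962 for the mean.

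Gene lists for muscle wasting, metabolism, contraction and inflammation, markers of other cell types that a muscle sample can hold, and checks on sex-linked and RNA-quality genes were fixed in advance; the 32 with at least 3 measured members were tested. Each list was compared with all other genes by limma's camera with a correlation between genes preset at 0.01, adjusted over the 32 lists, and again with an estimated correlation; under the latter no list in any comparison passed. Members were counted over all genes and adjusted over the list alone, and limma's fry was run beside camera. A list's median is given relative to the median of all genes. The groups, the model, the threshold, the lists, the rule for the genes named and the alternatives were fixed before the data were examined, unless the text says otherwise. By that rule the text names, per model, the 8 largest rises and 8 largest falls among called genes with a mean log2 value of at least 1 over the model's 4 libraries and no overlap between groups, passing over predicted genes and genes without a symbol. For the mean it names the 10 largest rises and 10 largest falls with the same sign in all 4 models, and for the F test the 10 genes with the smallest p. It also takes up to 4 members of each list with the smallest p, and 13 genes named whatever their values: Fbxo32, Trim63, Fbxo30, Foxo1, Foxo3, Mstn, Cebpd, Socs3, Pdk4, Ppargc1a, Myh4, Col1a1 and Col3a1. Not every gene that the rule takes is printed.

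Alternatives were quantile normalization, centring of each library on its median, a stricter filter (mean log2 value of at least 2), fits without the trend, with vooma weights or with robust variances, a block for the replicate number, adjusted p under 0.10, a log2 change of at least 1, only the 4 libraries of a model, each library or model left out in turn, and, chosen after the data were seen, voom weights from the recovered reads, scaling by the median of gene-wise differences and leaving out a pair of libraries. The code was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. For the KPP comparison, 72% of the former and 98% of the latter were called, and 0 genes were called in LLC, where none was changed. For the mean of the 4 models these were 98% and 100%, and for the F test 20% and 88%. Unchanged genes made up 13 of 183 calls in KPP, 10 of 208 for the mean and 11 of 119 for the F test. Each gene was simulated with the same spread in every library, unlike the real groups, so the 0 for LLC does not vouch for the real LLC calls. Gene positions are those of the GENCODE M21 annotation on GRCm38 and span the whole gene, exons and introns. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The outlier test between replicates was not run, since it needs groups of at least 4 samples.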

Results

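Gene expression was measured by sequencing total RNA, depleted of ribosomal RNA, from the tibialis anterior, a fast muscle of the lower leg. The mice had cancer cachexia, a wasting of muscle and fat that accompanies many tumours, or were controls. The labels name 4 mouse models, KPP, KPC, C26 and LLC, each with 2 control and 2 cachectic libraries. KPP and LLC mice were C57BL/6J, C26 mice were CD2F1 and KPC mice were of a mixed strain, so model and strain could not be separated. Each model had controls with its own strain label. The 16 libraries held 28584279 to 46972882 reads over the listed genes. Unless stated otherwise, a value beside a gene is its log2 change, cachectic minus control, ± SE, with n = 2 libraries per group. Tests were made with limma, and p-values were adjusted over all listed genes by the Benjamini-Hochberg method. The labels give n = 2 per group and do not state that the 2 are separate animals, so the p-values rest on the spread between samples. For each gene that spread was pooled over the 8 groups, which differed. The standard deviation of the log2 difference between replicates was 0.561 in LLC cachectic, 0.534 in KPC cachectic, 0.359 in KPP cachectic and 0.346 in C26 cachectic pairs. In controls it was 0.239 to 0.291. P-values for LLC and KPC thus rest on a smaller spread than their cachectic pairs showed. Every library expressed Y-linked genes, with Ddx3y at 7.69 in LLC cachectic 1 and 6.35 to 7.03 in the others on the log2 scale.

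Mitochondrially encoded genes took a smaller share of the reads in most cachectic libraries. Their share was 9.10% to 13.0% in the 8 control libraries and 5.73% to 8.91% in the cachectic libraries apart from KPC cachectic 2, which held 12.3%. Ttn, which encodes the giant sarcomere protein titin, took 15.5% to 20.9% of the reads of a library. Replicates correlated across genes with r = 0.990 in KPP controls, 0.990 in KPC controls, 0.993 in C26 controls and 0.992 in LLC controls. Among cachectic pairs, r was 0.984 in KPP and 0.985 in C26, but 0.965 in KPC and 0.964 in LLC. On the first 2 principal components KPC cachectic 2 (-23.0, -7.39) lay among control libraries, whereas KPC cachectic 1 lay at 11.3 and 24.0. LLC cachectic 1 (20.3, 42.8) lay apart from LLC cachectic 2 (-5.47, 21.3).

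**Figure D1:**
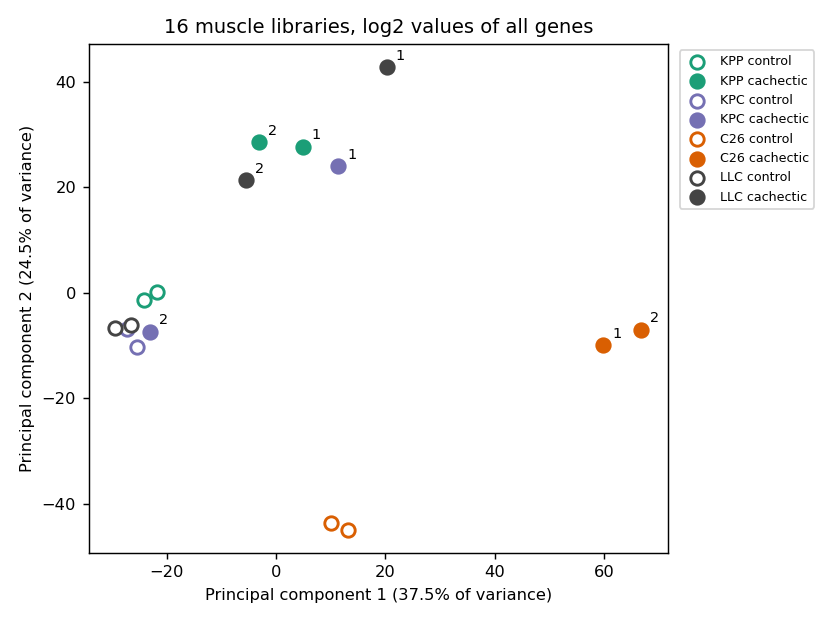
The 16 libraries on the first 2 principal components of the log2 values (37.5% and 24.5% of the variance). Marks give the model and whether the library was control (open) or cachectic (filled). KPC cachectic 2 lies at -23.0 and -7.39, among control libraries.

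In KPP muscle the largest rises included Lcn2, a secreted acute-phase protein that binds iron-loaded siderophores (4.87 ± 0.89, adjusted p = 0.0293), and Lgals3, a galectin (2.19 ± 0.40, adjusted p = 0.0293). Cdkn1a, the cell-cycle inhibitor p21, rose too (2.07 ± 0.46, adjusted p = 0.047). Sntb1, a syntrophin of the dystrophin-associated complex, rose by 2.49 ± 0.21 (adjusted p = 0.000441). It lies on chromosome 15 between 55636388 and 55906949 (GRCm38, minus strand). The largest falls included fibrillar collagens: Col1a1 (-3.55 ± 0.75), Col3a1 (-3.14 ± 0.61) and Col1a2 (-2.79 ± 0.54), with adjusted p = 0.0435, 0.0364 and 0.0364. Col1a1 lies on chromosome 11 between 94936224 and 94953042 (plus strand). Aplnr, the apelin receptor, also fell (-2.92 ± 0.39, adjusted p = 0.01). In all, 214 genes changed, 85 rising and 129 falling, and centring each library on its median gave 194, with 104 rising and 90 falling. The count was 8 without KPP control 1, 10 without KPP control 2, 12 without KPP cachectic 1 and 99 without KPP cachectic 2. Of the genes named for KPP, only Sntb1 kept its call whichever of the 4 libraries was left out.

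Extracellular matrix genes fell in KPP: 12 of 39 fell (27 adjusted over the list alone), and none of the 39 rose. Besides the collagens they included Mmp2, a gelatinase (-1.21 ± 0.15), Col15a1 (-2.09 ± 0.28) and Serpinh1, a collagen chaperone (-1.25 ± 0.18). The matrix median was -0.88 relative to all genes (camera adjusted p = 1.68e-14, adjusted p = 0.453 with an estimated correlation). Tendon markers lay lower beside them, with a median of -1.60 (camera adjusted p = 0.000324, adjusted p = 0.453 with an estimated correlation). Of 9 tendon markers, 0 passed over all genes, and 6 fell and 1 rose adjusted over the list alone. Thy1 (-2.05 ± 0.41) and Dpt (-1.47 ± 0.32) fell among 14 markers of fibroblasts and fibro-adipogenic progenitors.

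Genes of fatty acid oxidation fell in KPP (6 of 25, 13 adjusted over the list alone), led by Fabp3, which carries fatty acids in muscle (-1.77 ± 0.25), and Acads, an acyl-CoA dehydrogenase (-1.13 ± 0.21). Their median was -0.61 (camera adjusted p = 2.92e-08, adjusted p = 0.453 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.50 (camera adjusted p = 1.4e-14, adjusted p = 0.453 with an estimated correlation). None of these 40 passed over all genes, and 28 fell when adjusted over the list alone. The mitochondrial share of the reads was 5.89% and 5.73% in the cachectic KPP libraries, and 3 of 14 mitochondrially encoded and RNA-quality genes, a check list, fell and 0 rose over all genes, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000333, adjusted p = 0.453 with an estimated correlation).

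Genes that glucocorticoids induce lay higher in KPP, with a median of 0.97 (camera adjusted p = 4.91e-09, adjusted p = 0.453 with an estimated correlation). Those that rose (3 of 18, 13 adjusted over the list alone) were Glul, glutamine synthetase (1.58 ± 0.29), Pik3r1, a subunit of phosphoinositide 3-kinase (adjusted p = 0.047), and Klf15, a transcription factor (1.10 ± 0.24). Foxo3, a transcription factor that drives atrophy genes, rose by 1.05 ± 0.21, and lies on chromosome 10 between 42181841 and 42276755 (minus strand). FoxO factors and targets had a median of 0.61 (camera adjusted p = 0.000693, adjusted p = 0.453 with an estimated correlation), and 3 of 17 rose (6 adjusted over the list alone). Foxo6 fell against that list (-3.22 ± 0.72, adjusted p = 0.047), a call that centring ended. The ubiquitin ligase genes most used as marks of atrophy did not pass: Fbxo32 was 0.04 ± 0.56, adjusted p = 0.976, and Trim63 was 1.06 ± 0.58, adjusted p = 0.318. Of 18 ligase and atrophy genes, only Fbxo40 passed over all genes, and it fell (-0.73 ± 0.16), with 2 rose and 2 fell adjusted over the list alone.

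Slow fibre genes rose in KPP (3 of 11, with 4 rose and 1 fell adjusted over the list alone): Tnnt1, the slow troponin T (2.06 ± 0.46), Casq2 (1.52 ± 0.32) and Myh7b (1.47 ± 0.23). Their list stood apart from other genes (camera adjusted p = 0.00749, adjusted p = 0.453 with an estimated correlation). Myh3, the embryonic myosin of regenerating fibres, rose by 1.45 ± 0.29. Acute-phase and STAT3-responsive genes had a median of 0.75 (camera adjusted p = 1.91e-05, adjusted p = 0.453 with an estimated correlation), with Lcn2 past the threshold over all genes and 7 of 18 when adjusted over the list alone. Erythroid genes lay higher (camera adjusted p = 0.00378, adjusted p = 0.453 with an estimated correlation): 6 of 7 were positive, 6 rose adjusted over the list alone, and none of the 7 passed over all genes.

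In KPC muscle no gene differed between cachectic and control libraries after adjustment. Several genes had values in the direction seen elsewhere: Fbxo32, the ubiquitin ligase atrogin-1, was 1.42 ± 0.56, adjusted p = 0.566, and Socs3, an inhibitor of cytokine signalling, was 1.89 ± 0.55, adjusted p = 0.547. Col1a1 was -1.46 ± 0.75, adjusted p = 0.579, and Foxo6, a forkhead factor, was -2.18 ± 0.72, adjusted p = 0.547. With limma 0 genes passed, the smallest adjusted p was 0.269, and 1035 genes had an unadjusted p under 0.05. The fits without the trend, with vooma weights, with robust variances and with voom weights on the recovered reads each called 1 gene. It was Rprl3, an RNase P RNA gene, at 6.88, named here after its values were seen. KPC controls held no or almost no reads of it, so the size of this change depends on the 0.5 added to each count. The count was 949 without KPC cachectic 2, the library that lay among controls, 4 without KPC cachectic 1 and 1 without KPC control 1.

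Whole gene lists differed in KPC although no member passed over all genes. Nuclear genes of oxidative phosphorylation lay lower, 1 of 40 positive, with a median of -0.42 (camera adjusted p = 7.32e-14, adjusted p = 0.518 with an estimated correlation). Glycolysis and glycogen genes had a median of -0.30 (camera adjusted p = 0.00928, adjusted p = 0.631 with an estimated correlation), a call that quantile normalization ended. Extracellular matrix genes lay lower too, with a median of -0.41 (camera adjusted p = 4.36e-06, adjusted p = 0.548 with an estimated correlation), beside tendon markers at -0.77 (camera adjusted p = 0.000945, adjusted p = 0.518 with an estimated correlation). Acute-phase and STAT3-responsive genes lay higher, 17 of 18 positive, with a median of 0.72 (camera adjusted p = 8.55e-07, adjusted p = 0.518 with an estimated correlation). Among them Il4ra, an interleukin-4 receptor chain, was 1.03 ± 0.36.

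Macrophage markers also lay higher in KPC, 9 of 9 positive with a median of 0.63 (camera adjusted p = 0.00251, adjusted p = 0.548 with an estimated correlation), and C1qb, a complement component made by macrophages, was 0.95 ± 0.38. Endothelial markers had a median of 0.33 (camera adjusted p = 1.05e-05, adjusted p = 0.0976 with an estimated correlation), with Pecam1, an adhesion molecule of vessel walls, at 0.59 ± 0.19. Adjusted over the list alone, 1 of 13 endothelial markers rose, and 0 members of the matrix, tendon, acute-phase, macrophage, oxidative phosphorylation and glycolysis lists passed. Of 32 lists tested, 13 passed (8 higher, 5 lower), whereas 8 passed higher and 0 lower without KPC cachectic 1, so the oxidative phosphorylation, glycolysis, matrix and tendon lists then lost their calls.

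In C26 muscle, metallothionein and acute-phase genes were among the largest rises. Mt2, a metal-binding protein gene on chromosome 8 between 94172664 and 94173568 (plus strand), rose by 6.93 ± 0.89 (adjusted p = 0.00149), and Mt1 by 5.66 ± 0.96. Lcn2, on chromosome 2 between 32384633 and 32388252 (minus strand), rose by 5.75 ± 0.89 (adjusted p = 0.00331). Serpina3n, a secreted protease inhibitor gene on chromosome 12 between 104406729 and 104414329 (plus strand), rose by 5.31 ± 0.47 (adjusted p = 0.000385). Fbxo32, on chromosome 15 between 58175879 and 58214932 (minus strand), rose by 3.31 ± 0.56 (adjusted p = 0.00431). The largest falls included Mettl21e (-3.82 ± 0.54) and Mettl21c (-3.81 ± 0.53), lysine methyltransferase genes of muscle, and Nmrk2, a nicotinamide riboside kinase (-3.77 ± 0.90). Altogether 3409 genes changed, 2794 rising and 615 falling, while the median change of all genes was 0.28. After each library was centred on its median, 1952 changed, 840 rising and 1112 falling. The genes named for C26 kept their calls after centring unless stated, and list medians are relative to the median of all genes. The count was 191 without C26 control 1, 536 without C26 control 2, 1292 without C26 cachectic 1 and 716 without C26 cachectic 2. Mt2, Lcn2, Serpina3n, Fbxo32, Mettl21e, Mettl21c, Dbp, Arntl, Socs3, Idh2 and Pvalb kept their calls in each.

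Acute-phase and STAT3-responsive genes rose in C26 (16 of 18, 17 adjusted over the list alone, 12 after centring), including Bcl3 (3.04 ± 0.46), Il1r1, an interleukin-1 receptor (1.52 ± 0.24), and Socs3 (3.01 ± 0.55). Their median was 1.63 (camera adjusted p = 3.83e-07, adjusted p = 0.398 with an estimated correlation). NF-kB targets lay higher (camera adjusted p = 0.0484, adjusted p = 0.525 with an estimated correlation), with 8 of 14 rising, such as Icam1, an adhesion molecule (1.38 ± 0.24), and Sod2, a mitochondrial superoxide dismutase, falling (-0.82 ± 0.19). In that list 10 rose and 1 fell adjusted over the list alone. Macrophage markers rose beside them (8 of 9, 8 adjusted over the list alone, 5 after centring), among them Lyz2 (1.32 ± 0.23) and C1qa (1.48 ± 0.33), and the list passed (camera adjusted p = 0.00652, adjusted p = 0.525 with an estimated correlation). Endothelial markers rose (8 of 13, 9 adjusted over the list alone, 4 after centring), with Vwf, a clotting protein of vessel walls, at 1.36 ± 0.22 (camera adjusted p = 0.0194, adjusted p = 0.31 with an estimated correlation).

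Ubiquitin ligase genes rose in C26: Trim63, the ligase MuRF1 (2.23 ± 0.58), Fbxo31 (1.97 ± 0.34) and Ube4a (1.41 ± 0.27) were among 7 of 18 ligase and atrophy genes that rose, while Wwp1 fell (-0.47 ± 0.14). In that list 8 rose and 1 fell adjusted over the list alone, and it did not stand apart from other genes (camera adjusted p = 0.246). Of 30 autophagy and lysosome genes, 10 rose (10 adjusted over the list alone, 5 after centring), such as Map1lc3b, an autophagosome protein (1.61 ± 0.37), and the list did not pass (camera adjusted p = 0.102). Glucocorticoid-responsive genes rose (9 of 18, 9 adjusted over the list alone, 7 after centring), with Fkbp5, a co-chaperone of the glucocorticoid receptor, at 2.23 ± 0.45 and Pik3r1 at 1.83 ± 0.31. Their median was 0.62 (camera adjusted p = 0.0294, adjusted p = 0.525 with an estimated correlation). Acute-phase, NF-kB, macrophage, endothelial and glucocorticoid lists were the 5 that lay higher in C26. Not all of these 5 kept their calls without C26 control 1 or without C26 cachectic 2. Foxo3 rose by 1.28 ± 0.21, whereas Foxo6, on chromosome 4 between 120267079 and 120287349 (minus strand), fell (-3.40 ± 0.72).

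Nuclear genes of oxidative phosphorylation fell in C26 (26 of 40, 36 adjusted over the list alone), such as Cox7a1, a cytochrome oxidase subunit of muscle (-1.36 ± 0.32). Their median was -0.83 (camera adjusted p = 7.72e-24, adjusted p = 0.31 with an estimated correlation). Genes of the tricarboxylic acid cycle and mitochondrial biogenesis fell as a list (camera adjusted p = 1.52e-10, adjusted p = 0.31 with an estimated correlation), with 12 of 21 falling. Idh2, a mitochondrial isocitrate dehydrogenase (1.31 ± 0.21), and Nrf1 (0.81 ± 0.19) rose against it, and 15 fell and 2 rose adjusted over the list alone. Glycolysis and glycogen genes fell (6 of 22, 6 adjusted over the list alone), with Pkm, pyruvate kinase, at -1.20 ± 0.23 (camera adjusted p = 1.16e-07, adjusted p = 0.342 with an estimated correlation). The mitochondrial share of the reads was 7.21% and 8.04% in the cachectic C26 libraries. There 8 of 14 mitochondrially encoded and RNA-quality genes, a check list, fell and 1 rose over all genes, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.92e-07, adjusted p = 0.31 with an estimated correlation).

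Sarcomere and fast fibre genes fell in C26 (8 of 26, 8 adjusted over the list alone), with Pvalb, parvalbumin, at -1.59 ± 0.25 and Casq1, a calcium store protein, at -2.27 ± 0.46 (camera adjusted p = 7.46e-08, adjusted p = 0.136 with an estimated correlation). Myh4, the myosin of the fastest fibres, did not pass (-0.04 ± 0.19, adjusted p = 0.887). Creatine and polyamine genes fell (5 of 15), among them Ckmt2, mitochondrial creatine kinase (-1.72 ± 0.42), while Srm, spermidine synthase, rose (0.89 ± 0.30, a call that centring ended), and 5 fell and 2 rose adjusted over the list alone. That list passed (camera adjusted p = 0.000262, adjusted p = 0.127 with an estimated correlation). Amd1 (-2.82 ± 0.62) and Amd2 (-2.73 ± 0.61), of the same list, are near-identical genes between which reads may be shared. Myog, a myogenic factor that denervation also induces, rose by 2.05 ± 0.37, and Ache, acetylcholinesterase, fell (-1.74 ± 0.37). The denervation list went both ways, 6 rising and 4 falling of 18 (4 and 5 after centring), and 6 rose and 5 fell adjusted over the list alone. Sod2, Wwp1 and Srm were named for C26 after their values were seen, because they moved against their lists.

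Circadian clock genes went both ways in C26. Arntl, the clock activator BMAL1 on chromosome 7 between 113207465 and 113314126 (plus strand), rose by 3.05 ± 0.31. Dbp, a clock-output factor on chromosome 7 between 45705088 and 45710203 (plus strand), fell (-3.33 ± 0.29), as did Bhlhe41 (-2.04 ± 0.30) and Hlf (-1.40 ± 0.18). Of 18 clock genes 6 rose and 6 fell (3 and 8 after centring), and 6 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0027, adjusted p = 0.398 with an estimated correlation). Among matrix genes Mmp14, a matrix metalloproteinase, rose by 1.45 ± 0.15, and Col1a1 fell (-3.09 ± 0.75). Of 39 matrix genes 7 rose and 8 fell (2 and 10 after centring), 7 rose and 10 fell adjusted over the list alone, and the list lay lower (camera adjusted p = 0.00116, adjusted p = 0.525 with an estimated correlation). Tnmd, tenomodulin, fell with the collagens (-2.97 ± 0.73), and 3 of 9 tendon markers did, while Cilp rose (1.08 ± 0.34, a call that centring ended), and 4 fell and 1 rose adjusted over the list alone. Quantile normalization ended the calls of the clock list, the sarcomere and fast fibre list and the list of mitochondrially encoded and RNA-quality genes in C26.

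In LLC muscle erythroid genes were among the largest rises. Alas2, the enzyme that starts haem synthesis in erythroid cells, rose by 4.32 ± 0.58 (adjusted p = 0.00468), and lies on chromosome X between 150547375 and 150570638 (plus strand). The globin genes Hbb-bt and Hba-a1 rose by 4.14 ± 0.50 and 3.94 ± 0.48, and Hba-a1 lies on chromosome 11 between 32283511 and 32284465 (plus strand). In all 6 of 7 erythroid markers rose (6 adjusted over the list alone), with a median of 3.84 (camera adjusted p = 5.1e-08, adjusted p = 0.41 with an estimated correlation). Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical pairs that may share reads. Csrp3, the muscle LIM protein gene on chromosome 7 between 48830398 and 48848033 (minus strand), fell (-4.25 ± 0.74, adjusted p = 0.0136), as did Col1a1 (-4.21 ± 0.75) and Nmrk2 (-3.90 ± 0.90). A fit of only the 4 LLC libraries called 0 genes. With the spread pooled over all 16 libraries, 851 genes changed, 411 rising and 440 falling. The count was 77 without LLC control 1, 3 without LLC control 2, 69 without LLC cachectic 1 and 3711 without LLC cachectic 2. Of the genes named for LLC, none kept its call in all 4 of these. The sex-linked genes, a check on the samples, lay higher in LLC (camera adjusted p = 0.0291, adjusted p = 0.46 with an estimated correlation), with 0 of 4 rising over all genes and 4 adjusted over the list alone.

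Extracellular matrix genes fell in LLC (19 of 39), none of the 39 rising, and 30 fell and 1 rose adjusted over the list alone. They included Col1a2 (-3.23 ± 0.54), Col15a1 (-2.23 ± 0.28) and Col6a1 (-1.77 ± 0.30), and the median was -1.25 (camera adjusted p = 3.53e-16, adjusted p = 0.41 with an estimated correlation). Tendon markers fell beside them (5 of 9, 8 adjusted over the list alone), with Kera, keratocan, at -3.20 ± 0.82 and Tnmd at -3.12 ± 0.73. The tendon median was -2.35 (camera adjusted p = 4.32e-07, adjusted p = 0.41 with an estimated correlation). Fibroblast and progenitor markers had a median of -0.60 (camera adjusted p = 0.00817, adjusted p = 0.546 with an estimated correlation). Among these Thy1 fell (-2.20 ± 0.41), and 4 fell and 1 rose adjusted over the list alone.

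In LLC Fbxo32 (2.75 ± 0.56), Ube4a (1.78 ± 0.27) and Klhl38 (2.26 ± 0.40) were among 5 of 18 ligase and atrophy genes that rose (7 adjusted over the list alone), though the list did not pass (camera adjusted p = 0.0691). Trim63 was 1.65 ± 0.58, adjusted p = 0.0903. Autophagy and lysosome genes rose (7 of 30, 14 adjusted over the list alone), including Ctsl, the lysosomal protease cathepsin L (1.92 ± 0.47) (camera adjusted p = 0.000169, adjusted p = 0.498 with an estimated correlation). Proteasome subunit genes were positive in 31 of 31, and 0 passed over all genes or adjusted over the list alone. Their median was 0.66 (camera adjusted p = 4.23e-05, adjusted p = 0.582 with an estimated correlation). Mstn, myostatin, an inhibitor of muscle growth, rose by 0.95 ± 0.26 (adjusted p = 0.0499), and Id1, a target of BMP signalling, by 1.48 ± 0.24, while Smad3 fell (-1.22 ± 0.23).

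Glucocorticoid-responsive genes rose in LLC (6 of 18, 9 adjusted over the list alone), among them Glul (2.15 ± 0.29), Pik3r1 (1.78 ± 0.31) and Klf15 (1.45 ± 0.24). Their median was 1.19 (camera adjusted p = 4.27e-06, adjusted p = 0.424 with an estimated correlation). Foxo3 rose by 0.95 ± 0.21, Foxo6 fell (-3.08 ± 0.72), and 4 of 17 FoxO factors and targets rose (7 adjusted over the list alone) (camera adjusted p = 0.00422, adjusted p = 0.455 with an estimated correlation). Acute-phase and STAT3-responsive genes rose (6 of 18, 11 adjusted over the list alone), including Osmr, the oncostatin M receptor (1.41 ± 0.35) (camera adjusted p = 2.52e-05, adjusted p = 0.46 with an estimated correlation). Macrophage markers lay higher too, 9 of 9 positive with a median of 0.52 (camera adjusted p = 0.0384, adjusted p = 0.582 with an estimated correlation), and 1 rose over all genes (1 adjusted over the list alone). Of 22 interferon-stimulated genes only Rsad2, viperin, rose (2.06 ± 0.44, 1 adjusted over the list alone).

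Oxidative phosphorylation genes lay lower in LLC, with a median of -0.52 (camera adjusted p = 3.74e-10, adjusted p = 0.478 with an estimated correlation), and 2 of 40 fell (2 adjusted over the list alone). The mitochondrially encoded mt-Co2, a cytochrome oxidase subunit, fell (-0.82 ± 0.17), and the mitochondrial shares were 7.97% and 8.91%. In LLC 5 of 14 mitochondrially encoded and RNA-quality genes, a check list, fell and 0 rose over all genes, and 8 fell and 0 rose adjusted over the list alone (camera adjusted p = 4.23e-05, adjusted p = 0.424 with an estimated correlation). Actn2 (-1.15 ± 0.19), Myh1 (-0.94 ± 0.19) and Myh2 (-1.30 ± 0.30), genes of the contractile apparatus, fell, while Myh4 was 0.26 ± 0.19, adjusted p = 0.386. Of 26 sarcomere and fast fibre genes 4 fell, and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.46 with an estimated correlation), a list call that quantile normalization ended. Not all of the 9 lists that lay lower in LLC kept their calls without LLC cachectic 1, the library that lay apart.

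**Figure D2:**
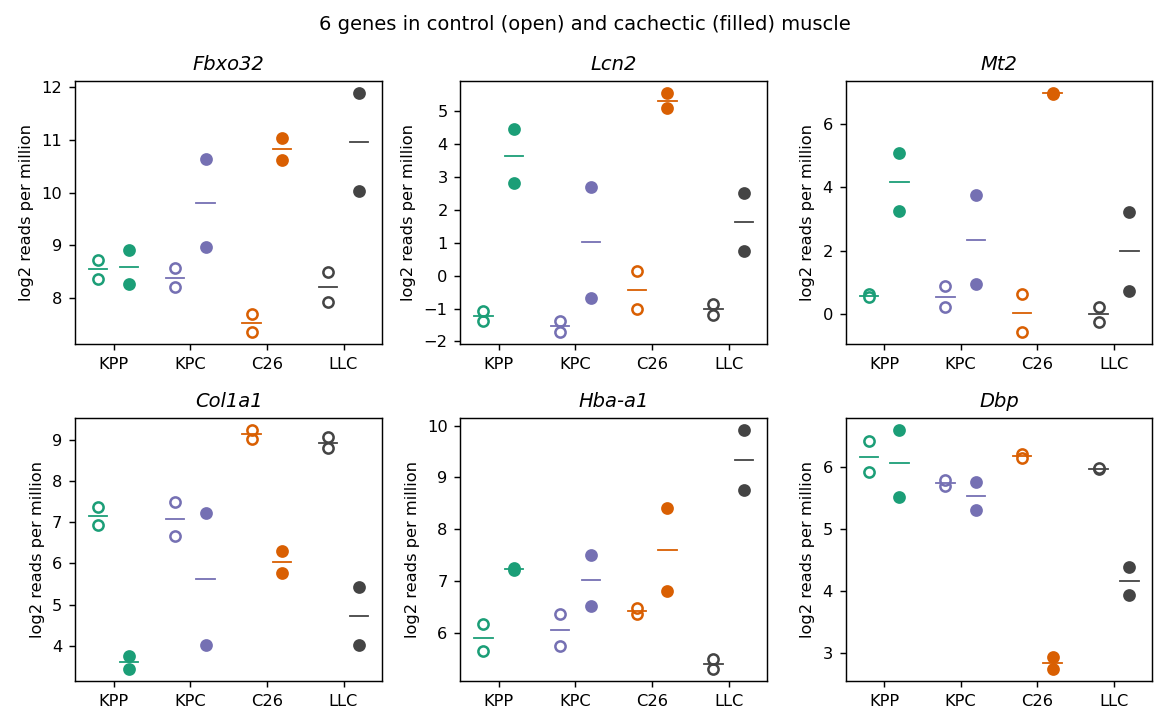
Log2 reads per 1000000 of Fbxo32, Lcn2, Mt2, Col1a1, Hba-a1 and Dbp in each of the 16 libraries, by model. Open marks are control libraries, filled marks cachectic libraries, and bars the mean of the 2. Hba-a1 rose by 3.94 in LLC, and Mt2 rose by 6.93 in C26, where Dbp fell (-3.33).

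Averaged over the 4 models (8 cachectic and 8 control libraries, each model against its own controls), Lcn2, Mt2, Serpina3n and Fbxo32 were among the genes that rose, and Col1a1 among those that fell. Lcn2 rose by 3.95 ± 0.45, Mt2 by 3.57 ± 0.45 and Serpina3n by 2.45 ± 0.23 (adjusted p = 0.000371, 0.000417 and 0.000368). Fbxo32 rose by 1.88 ± 0.28, Foxo3 by 0.91 ± 0.10 and Acer2, a ceramidase, by 1.96 ± 0.23. Col1a1 (-3.08 ± 0.37), Nrep (-2.95 ± 0.34), Foxo6 (-2.97 ± 0.36) and Bdh1, a mitochondrial enzyme of ketone use (-2.23 ± 0.34), fell. In all 4938 genes changed, 3284 rising and 1654 falling, with a median of 0.10 over all genes. After centring 4638 changed, 2383 rising and 2255 falling, and after quantile normalization 2321 rose and 2390 fell. Of the 4938, 4003 (81.1%) had the same sign in all 4 models, which choosing genes by their mean favours, and 5211 (43.3%) of all genes had. Leaving out 1 library at a time gave 3892 to 6210 genes, and leaving out the C26 model gave 1753, 746 rising and 1007 falling. Leaving out both KPC cachectic 2 and LLC cachectic 1, a pair chosen after the data were seen, gave 6218.

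Acute-phase and STAT3-responsive genes rose in the average (17 of 18, 18 adjusted over the list alone), among them Socs3 (1.82 ± 0.28), Il4ra (1.44 ± 0.18) and Cebpd, a transcription factor of the acute phase (2.09 ± 0.39) (camera adjusted p = 1.14e-07, adjusted p = 0.287 with an estimated correlation). Macrophage markers rose beside them (7 of 9, 7 adjusted over the list alone) (camera adjusted p = 0.00896, adjusted p = 0.626 with an estimated correlation), as did erythroid markers (6 of 7, with 6 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.00155, adjusted p = 0.314 with an estimated correlation). Glucocorticoid-responsive genes rose (16 of 18, 16 adjusted over the list alone), with Glul at 1.32 ± 0.15 (camera adjusted p = 1.47e-05, adjusted p = 0.287 with an estimated correlation). Of 17 FoxO factors and targets 11 rose and Foxo6 fell, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00212, adjusted p = 0.287 with an estimated correlation).

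Among 18 ligase and atrophy genes, 8 rose in the average, with Trim63 at 1.42 ± 0.29 and Klhl38 at 1.41 ± 0.20, while Fbxo40 (-0.36 ± 0.08) and Wwp1 (-0.25 ± 0.07) fell. In that list 8 rose and 3 fell adjusted over the list alone, and it did not pass (camera adjusted p = 0.466). Fbxo30, a ligase gene of the same list, was -0.02 ± 0.09, adjusted p = 0.851. Of 30 autophagy and lysosome genes 13 rose, with Gabarapl1, an autophagosome protein, at 0.75 ± 0.13, and Ulk2 fell (-0.27 ± 0.07), and 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.71 with an estimated correlation). Proteasome subunits lay higher as a list, 31 of 31 positive with a median of 0.26 (camera adjusted p = 0.025, adjusted p = 0.844 with an estimated correlation). Only 6 of the 31 rose over all genes (0 adjusted over the list alone), with Psmd4 at 0.77 ± 0.24. Among single models that list passed in LLC alone. In KPP its median was -0.09, with 8 of 31 positive (camera adjusted p = 0.783). It did not pass in KPC (camera adjusted p = 0.193) or C26 (camera adjusted p = 0.151).

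Nuclear genes of oxidative phosphorylation fell in the average (38 of 40), with Cox7a1 at -1.04 ± 0.16 and Ndufs8, of complex I, at -0.68 ± 0.10, and only Cox6a2 rose (0.23 ± 0.08, a call that centring ended). In that list 39 fell and 1 rose adjusted over the list alone, and the median was -0.58 (camera adjusted p = 3.9e-21, adjusted p = 0.287 with an estimated correlation). Beside it 10 of 14 mitochondrially encoded and RNA-quality genes, a check list, fell and 1 rose over all genes, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.47e-05, adjusted p = 0.287 with an estimated correlation). Of 21 tricarboxylic acid cycle and mitochondrial biogenesis genes 16 fell, Idh2 (1.02 ± 0.11) and Nrf1 (0.47 ± 0.10) rose, and 17 fell and 2 rose adjusted over the list alone (camera adjusted p = 2.46e-08, adjusted p = 0.287 with an estimated correlation). Glycolysis and glycogen genes fell (11 of 22), with Pgam2, a muscle phosphoglycerate mutase, at -0.83 ± 0.16, against Gpi1 (0.36 ± 0.10) and Pgm2 (0.45 ± 0.12), which rose. There 13 fell and 3 rose adjusted over the list alone (camera adjusted p = 6.49e-05, adjusted p = 0.389 with an estimated correlation). Creatine and polyamine genes fell (8 of 15), with Gamt, which makes creatine, at -1.04 ± 0.18, and only Sat1 rose (0.50 ± 0.10), with 8 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000429, adjusted p = 0.163 with an estimated correlation).

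Matrix genes fell in the average (26 of 39), with Sparc, a collagen-binding protein, at -1.12 ± 0.12, against Lox (0.69 ± 0.20), Eln (0.53 ± 0.13), Thbs1 (0.39 ± 0.15, a call that centring ended) and Mmp14 (0.52 ± 0.08), which rose. There 27 fell and 4 rose adjusted over the list alone, and the median was -0.71 (camera adjusted p = 6.17e-13, adjusted p = 0.287 with an estimated correlation). Tendon markers fell beside them (7 of 9, 7 adjusted over the list alone), with Chad, chondroadherin, at -2.56 ± 0.37 (camera adjusted p = 7.19e-06, adjusted p = 0.287 with an estimated correlation). The members named for the average because they moved against their lists (Fbxo40, Wwp1, Ulk2, Cox6a2, Nrf1, Gpi1, Pgm2, Sat1, Lox, Eln, Thbs1 and Mmp14) were named after their values were seen.

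**Figure D3:**
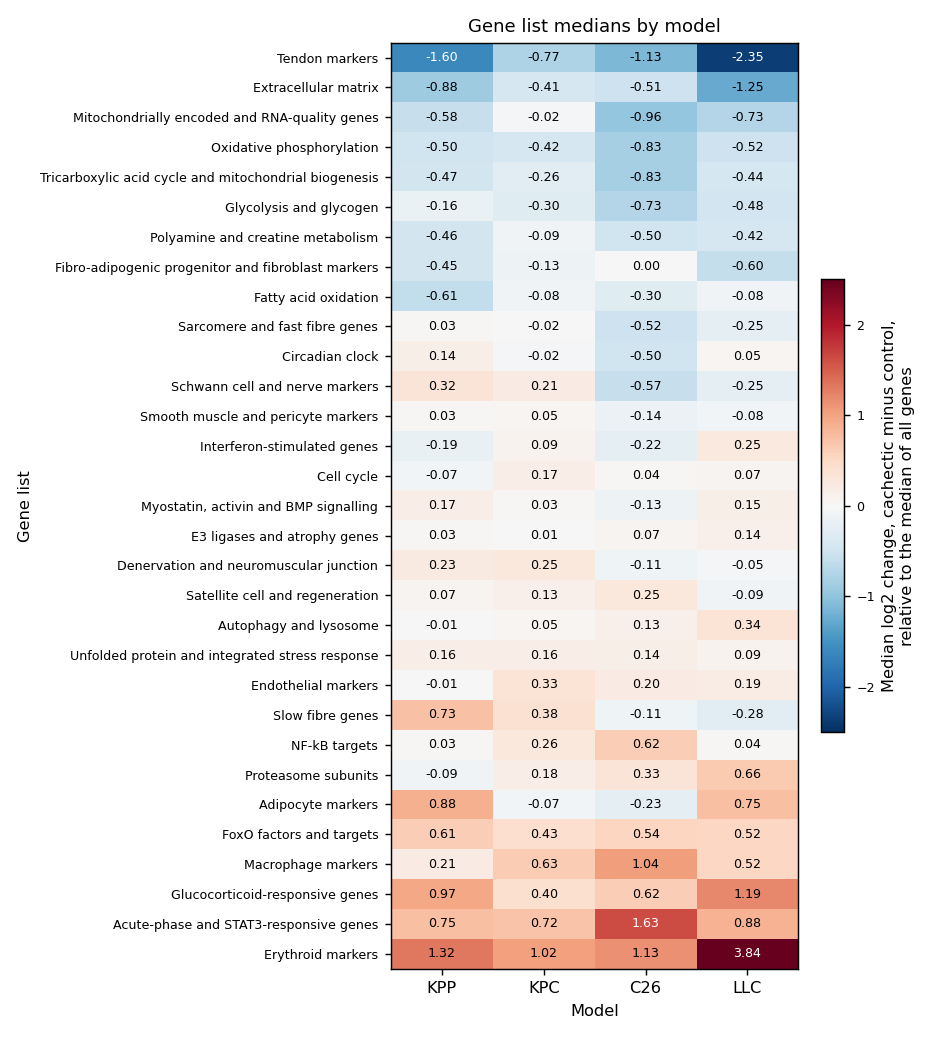
Median log2 change of each gene list in each of the 4 models, relative to the median of all genes. The color scale runs from -2.5 (lower in cachectic muscle) to 2.5 (higher). Erythroid markers have a median of 3.84 in LLC, and extracellular matrix genes of -0.88 in KPP, -0.41 in KPC, -0.51 in C26 and -1.25 in LLC.

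The response of Sntb1 differed between the models: it rose in KPP and had smaller values elsewhere (2.49 in KPP, 0.09 in KPC, 0.45 in C26, -0.43 in LLC, F test adjusted p = 0.0207). Dbp was -0.10 in KPP, -0.20 in KPC, -3.33 in C26, -1.81 in LLC, and Arntl was -0.46 in KPP, -0.09 in KPC, 3.05 in C26, 0.08 in LLC (adjusted p = 0.0255 for each). Usp2, a clock-controlled ubiquitin protease, was 0.62 in KPP, -0.25 in KPC, -1.07 in C26, 0.04 in LLC (adjusted p = 0.0439). Adamtsl5, a secreted matrix protein, was 0.24 in KPP, -0.04 in KPC, 0.11 in C26, -1.61 in LLC (adjusted p = 0.0207). Mmp2 was -1.21 in KPP, -0.44 in KPC, 0.49 in C26, -0.51 in LLC (adjusted p = 0.0289), a call that centring ended. The F test over the 4 models called 14 genes. It called 0 without KPP control 1, KPP control 2, KPC control 1, C26 control 1, C26 control 2, LLC control 1 or LLC control 2, and 9 without KPC control 2 or C26 cachectic 2. It called 60 without KPC cachectic 2, 255 without KPC cachectic 1, 174 without LLC cachectic 1 and 1404 without LLC cachectic 2.

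Between KPP and C26, Dbp (3.22 ± 0.41) and Tcap, the sarcomere protein telethonin (1.46 ± 0.27), had the higher change in KPP. Arntl (-3.52 ± 0.44), Serpina3n (-3.58 ± 0.66) and Mmp14 (-1.26 ± 0.22) had the higher change in C26. Fbxo32, which rose in C26 and did not pass in KPP, differed by -3.27 ± 0.79 and missed the threshold (adjusted p = 0.0807). In all 36 genes differed, 5 with the higher change in KPP and 31 in C26, and centring gave 17, with 11 and 6. The count was 0 without KPP control 2, 2 without C26 control 1 or C26 control 2, 6 without KPP control 1, 9 without KPP cachectic 1, 10 without C26 cachectic 2 and 19 without KPP cachectic 2. Slow fibre genes had the higher change in KPP, with a median of 1.37 (camera adjusted p = 3.54e-05, adjusted p = 0.284 with an estimated correlation). None of these 11 passed over all genes, and adjusted over the list alone 5 had the higher change in KPP and 1 in C26.

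Between C26 and LLC, Prg4, the joint lubricant lubricin (3.56 ± 0.53), and Igf1, a growth factor of muscle (1.81 ± 0.30), had the higher change in C26. They were among 14 genes that differed, all with the higher change in C26, and centring left 0. Hba-a1, which rose in LLC, differed by -2.75 ± 0.68 without passing (adjusted p = 0.12). Erythroid markers as a list had the lower change in C26, with a median of -2.76 (camera adjusted p = 1.61e-13, adjusted p = 0.138 with an estimated correlation). None of these 7 passed over all genes, and 7 did adjusted over the list alone. The count was 0 without C26 control 1, C26 control 2, LLC control 1 or LLC control 2, 3 without C26 cachectic 1, 194 without LLC cachectic 2 and 309 without LLC cachectic 1.

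Between KPP and LLC, 4 genes differed, all 4 with the higher change in KPP: Sntb1 (2.92 ± 0.30), Adamtsl5 (1.85 ± 0.22), the non-coding RNA Mirg (3.48 ± 0.42) and Fhl1, a LIM protein gene of muscle (2.69 ± 0.38). Leaving out KPP control 1 or LLC control 2 gave 1, KPP cachectic 1 or KPP cachectic 2 gave 8, and LLC cachectic 2 gave 1265. Between KPP and KPC, 3 genes differed: Sntb1 (2.40 ± 0.30), Ccdc141 (1.74 ± 0.25) and 1700001O22Rik (-4.67 ± 0.66). None of these 3 genes kept its call between KPP and KPC when 1 library of either model was left out, except without KPC cachectic 1. Ccdc141, 1700001O22Rik, Fhl1, Tcap, Prg4 and Igf1, and Serpina3n and Mmp14 for the differences between models, were named after their values were seen.

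Between KPC and C26, Dbp had the higher change in KPC (3.12 ± 0.41), and 6 genes in C26, among them Arntl (-3.15 ± 0.44) and Serpina3n (-4.42 ± 0.66). Centring left 1 of these 7. Leaving out KPC control 1, KPC control 2, C26 control 1, C26 control 2 or C26 cachectic 2 gave 0, KPC cachectic 2 or C26 cachectic 1 gave 2, and KPC cachectic 1 gave 378. Between KPC and LLC, limma called 0 genes (1004 at an unadjusted p under 0.05), with 1 in the fit without the trend and 2 with voom weights. Leaving out KPC cachectic 2 gave 1, KPC cachectic 1 gave 28 and LLC cachectic 2 gave 941.

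The responses of each pair of models correlated positively across genes, from Pearson's r = 0.510 for KPP with KPC to 0.652 for C26 with LLC (Spearman's rho 0.489 and 0.614). No p-value is given, since genes are not independent replicates. Without KPC cachectic 1, r was 0.0850 for KPP with KPC, 0.159 for KPC with C26 and 0.107 for KPC with LLC. Foxo3, Klf15, Glul and Pik3r1 were among 24 genes that rose in KPP, C26 and LLC alike, against 0.675 for independent lists. Col1a1, Col1a2, Cilp2, a cartilage matrix protein, and Sparc were among 26 that fell in all 3, against 0.242. In KPC, 22 of the 24 and 26 of the 26 had the same sign without passing the test. C26 and LLC shared 255 rising genes, against 95.5 for independent lists, and 152 falling genes, against 22.5, while 12 of 419 called in both went opposite ways. KPP shared 50 rising and 42 falling genes with C26 (19.8 and 6.60 for independent lists), and 32 and 46 with LLC (2.91 and 4.72). Each gene had 1 estimate of its spread for all models, so calls in different models are not independent. The numbers for independent lists may thus be too low.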

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

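The test without the 20 most abundant genes and the comparison of read totals were chosen after their results were seen, and the tests by thinning and by gene length before. The responses of the models to cachexia differed between groups in a test of the difference itself for 5 of the 6 pairs of models. The counts were 3 genes between KPP and KPC, 36 between KPP and C26, 4 between KPP and LLC, 7 between KPC and C26 and 14 between C26 and LLC. Leaving out 1 library gave 0 (without KPP control 1) to 14 (without KPC cachectic 1) for KPP and KPC, and 0 (without KPP control 2) to 41 (without C26 cachectic 1) for KPP and C26. It gave 1 (without KPP control 1) to 1265 (without LLC cachectic 2) for KPP and LLC, 0 (without KPC control 1) to 378 (without KPC cachectic 1) for KPC and C26, and 0 (without C26 control 1) to 309 (without LLC cachectic 1) for C26 and LLC.

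Over all 4 models the F test set apart Sntb1, a syntrophin, Acad12, an acyl-CoA dehydrogenase, and Adamtsl5, a secreted matrix protein (adjusted p = 0.0207 for each), and the clock genes Dbp and Arntl (adjusted p = 0.0255 for each). Mirg, a non-coding RNA, Mmp2, a gelatinase, and Lama3, a laminin chain, had an adjusted p of 0.0289, Trmt61a, a tRNA methyltransferase, of 0.038 and Usp2, a ubiquitin protease, of 0.0439. Acad12 was -0.48 in KPP, 0.06 in KPC, 1.21 in C26, 0.41 in LLC, and Lama3 was -0.16 in KPP, 0.18 in KPC, 1.69 in C26, -0.28 in LLC. Trmt61a was -0.56 in KPP, -0.34 in KPC, 1.33 in C26, 0.15 in LLC, and Mirg was 2.04 in KPP, -0.36 in KPC, 0.00 in C26, -1.45 in LLC. The calls of Mmp2, Lama3 and Trmt61a ended when each library was centred on its median. The F test called 0 genes without KPP control 1, KPP control 2, KPC control 1, C26 control 1, C26 control 2, LLC control 1 or LLC control 2, 9 without KPC control 2 or C26 cachectic 2, 60 without KPC cachectic 2, 174 without LLC cachectic 1, 255 without KPC cachectic 1 and 1404 without LLC cachectic 2. Strain and tumour model vary together here, and with anything else that differed between the models' samples. The design thus does not tell which of these the differences follow.

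Rises outnumbered falls among the genes called in C26 (2794 against 615), with a median change of 0.28 over all genes. A smaller share of the 20 most abundant genes is argued against as the main cause, since the median was 0.195 with these left out of the totals. Over 5 classes of exon length the median rose with length, from 0.219 in the shortest to 0.311 in the longest. A trend with gene length was thus present, but is argued against as the main cause, since even the lowest class median was 0.219. The median was 0.279 with every library thinned to the reads of the shallowest, which decides nothing because values relative to a library's own total hardly move under thinning, but a difference in depth, or fewer reads in 1 group, is argued against by the totals: 39125408 and 33290109 reads in controls, 39291166 and 29933182 in cachectic libraries, whose mean was 95.6% of that of controls. The deposited values are scaled to each library's own total and centring fixes the median by construction, so how much of the shift comes from that scaling was not decided, and the balance after centring was 840 rises and 1112 falls. A biological shift of C26 muscle toward more of the less abundant transcripts stays open and untested.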

How the results depend on the processing

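Voom weights, scaling by the median of gene-wise differences and leaving out a pair of libraries were chosen after the data were seen, and the other alternatives before. Every correlation kept its sign, but the balance of rises and falls turned over in places. The filter on low values removed no gene, so a fit without it moves nothing and was not run as a separate setting. Where a count moved, the cause was not tested unless stated.

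Scaling moved the C26 results most: C26 called 2052 genes after quantile normalization, 1952 after median centring and 2003 after scaling by the median of differences, against 3409. The balance in C26 was then 956 rises and 1096 falls, 840 and 1112, and 755 and 1248, against 2794 and 615. In KPP it was 137 and 113 after quantile normalization, 104 and 90 after median centring and 105 and 76 after the median of differences, against 85 and 129. Between KPP and C26, 19 genes had the higher change in KPP and 16 in C26 (quantile normalization), 11 and 6 (median centring), and 18 and 10 (median of differences), against 5 and 31. In the mean it was 2321 and 2390 after quantile normalization and 2249 and 2388 after the median of differences, against 3284 and 1654. KPC and C26 differed in 0 genes (quantile normalization), 1 gene, Dbp (median centring), and 0 genes (median of differences), against 7. Median centring gave 17 genes for KPP and C26 and 0 for C26 and LLC, and the median of differences gave 0 for C26 and LLC and 9 for the F test. A stricter filter, with fewer genes tested, gave 8 genes for the F test and 1, Sntb1, for KPP and KPC.

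The variance model moved KPP and the smallest counts. Without the trend KPP called 94 genes and KPC 1 (Rprl3), while KPP and KPC differed in 5 (Sntb1, Ccdc141, Rassf9, 1700001O22Rik and Rprl3) and KPC and LLC in 1 (Rprl3). With vooma weights KPP called 108 genes and KPC 1 (Rprl3), and KPP and KPC differed in 1 (Sntb1). Robust variances called 1 gene in KPC (Rprl3) and 0 for KPC and C26. Voom weights from the recovered reads called 1 gene in KPC (Rprl3), 2 for KPC and LLC (Rprl3 and Adamtsl5) and 27 for C26 and LLC. Fitting only the 4 libraries of a model gave 1124 genes in KPP, 5152 in C26 and 0 in LLC, where limma had called 851 with all 16 libraries and 3523 had an unadjusted p under 0.05. Alas2 then had an adjusted p of 0.0759 in LLC.

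A block for the replicate number gave 53 genes in KPP and 477 in LLC, 1 for the F test, 0 for KPP and KPC, 4 for KPP and C26 (Ciart, Arntl, Acad12 and Dbp), 8 for KPP and LLC, 1 (Dbp) for KPC and C26, and 0 for C26 and LLC. Pairing by these numbers is not borne out by the values, since equal numbers did not deviate together (r = 0.0894 in KPP, -0.003 in KPC, -0.0373 in C26 and 0.0207 in LLC), and the block spends degrees of freedom.

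By construction, an adjusted p under 0.10 called more genes: 887 in KPP, 2106 in LLC, 52 by the F test, 367 for KPP and C26, 16 for KPC and C26 and 111 for C26 and LLC. A log2 change of at least 1 called fewer: 117 in KPP, 874 in C26, 398 in LLC and 317 in the mean. Without the C26 model the mean called 1753 genes, 746 rising and 1007 falling. The counts for the mean stayed within 1.5 times of 4938 under the scalings, variance models, block and filter.

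Leaving out each library in turn leaves a group with 1 library, which is assumed to vary like the others. The counts ran from 8 (without KPP control 1) to 99 (without KPP cachectic 2) in KPP, 0 (without KPC control 2) to 949 (without KPC cachectic 2) in KPC, 191 (without C26 control 1) to 1292 (without C26 cachectic 1) in C26, 3 (without LLC control 2) to 3711 (without LLC cachectic 2) in LLC and 3892 (without LLC control 1) to 6210 (without LLC cachectic 2) in the mean. The F test ran from 0 (without KPP control 1, among others) to 1404 (without LLC cachectic 2). Between models the counts ran from 0 to 14 for KPP and KPC, 0 to 41 for KPP and C26, 1 to 1265 for KPP and LLC, 0 to 378 for KPC and C26, 0 to 941 for KPC and LLC and 0 to 309 for C26 and LLC. Correlations ran from 0.0850 to 0.596 for KPP with KPC, 0.480 to 0.543 for KPP with C26, 0.494 to 0.589 for KPP with LLC, 0.159 to 0.684 for KPC with C26, 0.107 to 0.638 for KPC with LLC and 0.486 to 0.676 for C26 with LLC. The 3 lowest with KPC came without KPC cachectic 1. Over called genes only, r was 0.702 for KPP with KPC, 0.664 for KPP with C26, 0.724 for KPP with LLC, 0.729 for KPC with LLC and 0.738 for C26 with LLC. Choosing genes by their changes in the same libraries favours a higher r.

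Of 32 gene lists, camera with an estimated correlation called 0 in KPP, 0 in KPC, 0 in C26, 0 in LLC and 0 in the mean, against 14, 13, 16, 18 and 17 with the preset correlation. The fry test called 1 in KPP, 1 in KPC, 15 in C26, 10 in LLC and 21 in the mean. Leaving out 1 library gave 12 to 15 lists in KPP, 8 to 14 in KPC, 14 to 19 in C26, 15 to 21 in LLC and 15 to 18 in the mean. In C26 5 lists were higher and 11 lower, against 8 and 5 after quantile normalization and 8 and 8 after median centring. Quantile normalization ended the C26 calls of Sarcomere and fast fibre genes (adjusted p = 0.0782), Circadian clock (0.0671), Mitochondrially encoded and RNA-quality genes (0.0528), Tendon markers, Interferon-stimulated genes and Schwann cell and nerve markers, and median centring ended the last 3. It also ended those of Glycolysis and glycogen in KPC and LLC, of Sarcomere and fast fibre genes in LLC and the mean, and of Endothelial markers in the mean, the last of which median centring ended too. Of the results for single named genes, 687 kept their side of the threshold under median centring, 33 no longer passed, 8 newly passed and 2 without a test moved. With every library thinned to the reads of the shallowest, C26 called 3227 genes against 3409, but so small a loss of reads does not show how far depth limits the count.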

Other observations

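S100a9, a calcium-binding protein that neutrophils make in quantity, rose in KPP (5.40 ± 1.13, adjusted p = 0.0435), C26 (5.05 ± 1.13, adjusted p = 0.0113) and LLC (6.19 ± 1.13, adjusted p = 0.0152). It was 4.55 ± 1.13, adjusted p = 0.547 in KPC and rose in the mean of the 4 models (5.30 ± 0.57, adjusted p = 0.000368). Only 2 of 12 neutrophil markers were measured, so the list was not tested. Ighm, the heavy chain of immunoglobulin M, fell in C26 (-3.51 ± 0.87, adjusted p = 0.0157) and in the mean (-2.62 ± 0.43, adjusted p = 0.00129). S100a9 and Ighm were named after their values were seen. Fat cell markers lay higher in KPP, with a median of 0.88 (camera adjusted p = 0.00749, adjusted p = 0.453 with an estimated correlation), and in LLC, with a median of 0.75 (camera adjusted p = 0.0458, adjusted p = 0.546 with an estimated correlation). Of the 11 measured, 0 rose in KPP and 1 in LLC, and the numbers were the same adjusted over the list alone.

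In C26, fatty acid genes parted: Acot1 (2.94 ± 0.70) and Acot2 (2.02 ± 0.52), thioesterases that release fatty acids from coenzyme A, and Cd36, a fatty acid transporter (1.12 ± 0.18), rose, while Hadh, an enzyme of fatty acid oxidation, fell (-0.61 ± 0.17). Ppard rose with them, a call that centring ended, so that 4 of 25 rose and 1 fell (3 and 3 after centring), the same numbers as those adjusted over the list alone without centring, and the list did not pass (camera adjusted p = 0.102). Myl3, a slow myosin light chain (-2.08 ± 0.59), and Mb, myoglobin (-1.53 ± 0.46), fell in C26. Runx1, a transcription factor that denervation induces, rose there (1.44 ± 0.26), and Cdh4, a cadherin of the same list, fell (-3.16 ± 0.79, named after its values were seen). The count of genes called in C26 was 191 without C26 control 1, 536 without C26 control 2, 1292 without C26 cachectic 1 and 716 without C26 cachectic 2.

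Of the tests that follow, the label exchange, the response score, the 2 on fibroblast markers and the strain genes used to place KPC cachectic 2 among the models were chosen after the result was seen, and the others before. Splits of the libraries within models were tested for the mean of the 4 models: of 100 splits drawn from 648, 1, the real one, gave as many genes (4938), and the highest other gave 1935. Chance is thus unlikely to give that count, though 100 splits cannot show a share below 1 of 100. The splits also take the libraries of a model to be separate animals, which the labels do not state.

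KPC cachectic 2 lay with the control libraries. An exchange of labels with a KPC control is argued against, since the higher of the 2 controls' response scores was 0.0381, on a scale where the response of the other models is 1. A library from another model's mice was first tested by its position between the KPP and LLC controls (0) and the KPC controls (1), which was 0.610 and decided nothing by the bounds set. Genes that separate strains argue against a C26 library, and less firmly against a KPP or LLC library. At 55 of 66 the library lay nearer to KPP and LLC than to the C26 mice, unlike a C26 library. At 4 (Gm12191, Rpl30-ps9, Rpl30-ps10 and Rab6b) it lay with both KPC controls nearer to C26, unlike KPP or LLC libraries. These 4 count for less than 4 independent genes. On a scale of 0 for KPP and LLC and 1 for C26, Rab6b lay at 0.515, just past the midpoint. Rpl30-ps9 and Rpl30-ps10 are copies of 1 gene that may share reads, and they lay at 1.04 and 1.03, with Gm12191 at 1.06. Gm12191 spans almost the same length and had like values in both strains, so it may be another such copy. The case against a KPP or LLC library may then rest on 1 signal besides Rab6b. A KPC mouse without cachexia that carries the cachectic label cannot be told apart from a cachectic mouse with little response in this muscle, since the response score was 0.0821 (0.888 in KPC cachectic 1) and the labels give no body weight. No biological explanation was tested.

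Collagen and tendon genes were lower in cachectic muscle together. Fewer fibroblasts are argued against only weakly as the main cause for Col1a1, Col1a2 and Col3a1, collagens among the largest falls in KPP. The median fibroblast and progenitor marker fell by 10.9% (SE 8.37) of their median fall (-2.37). That value clears the bound set for this test by less than 2 standard errors. The SE is taken over the 14 markers, which are not independent, and leaves out the spread between libraries. For the matrix genes as a list, fewer fibroblasts cannot be told apart from lower expression. The marker median was 42.4% (SE 32.7, taken the same way) of the list's median fall. These markers went both ways in the mean, 5 of 14 falling and 4 rising (5 and 4 adjusted over the list alone). They lay lower in KPP, with a median of -0.45 (camera adjusted p = 0.0238, adjusted p = 0.759 with an estimated correlation), and in LLC, with a median of -0.60 (camera adjusted p = 0.00817, adjusted p = 0.546 with an estimated correlation). Less tendon in the dissected samples cannot be told apart from lower expression: the highest and lowest of the tendon markers' mean changes lay 2.57 (SE 0.42) apart, from Tnmd (-2.73), Kera (-2.69) and Chad (-2.56) to Cilp (-0.19) and Scx (-0.16), which passes the bound of 2 by less than 2 standard errors. In single models Cilp (1.08) and Thbs4 (0.63) were higher in C26, and Scx (1.41) in KPP, values that go against less tendon for these markers but not for the others. Lower collagen expression in cachectic muscle stays open.

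Rprl3, an RNase P RNA gene on chromosome 8 between 3803069 and 3803358 (minus strand), was 1.31 and 1.47 on the log2 scale in cachectic KPC muscle, -6.24 and -4.74 in KPC controls, 1.48 to 2.10 in C26 libraries and -6.55 to -3.75 elsewhere. The values in KPC controls stand for no or almost no reads. The hypothesis was that cachectic and control KPC mice, of a mixed background, carry different alleles of a wide region or of many genes. Among 66 genes that set the C26 libraries apart from all KPP and LLC libraries by at least 2 on the log2 scale, only Rprl3 had both cachectic KPC libraries nearer to 1 strain and both KPC controls nearer to the other. Gm10240, whose values had been seen before the test, did not, and 0 genes besides these did. At 5 genes KPC cachectic 2 alone lay nearer to the strain that the other KPC libraries were not near, and at 2 KPC cachectic 1 alone did. The 5 (Gm12411, Rpl21-ps15, Gm10240, Gm10163 and Gm13370) lay at 0.698 to 0.767 in KPC cachectic 2, where 0 is KPP and LLC and 1 is C26. They span almost the same length, so they may be copies of 1 gene that share reads and count for less than 5 genes. At 52 of the 66 genes all 4 KPC libraries lay nearer to the C57BL/6J mice, and the test sees only alleles that set CD2F1 apart. The values thus argue only against a wide division of the groups by alleles of the CD2F1 kind. Other alleles of the mixed background, a difference at Rprl3 alone, or one between single mice, stay open and untested. Rpph1, also an RNase P RNA gene and one of the 66, was 5.37 and 7.22 in cachectic KPC muscle, 4.98 to 5.84 in C26 libraries and 7.88 to 9.05 elsewhere. On a scale of 0 for KPP and LLC and 1 for C26, it lay at 0.985 in KPC cachectic 1 and 0.402 in KPC cachectic 2. KPC controls lay at 0.0516 and -0.0644, so Rpph1 moved toward C26 in both cachectic libraries, though past the midpoint only in KPC cachectic 1. Whether Rprl3 and Rpph1 share reads was not tested.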
